A study of Mus musculus with 6 samples.

How the data were processed

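6 samples of RNA from mouse embryonic stem (ES) cells were labelled with biotin and hybridised to 1-colour expression arrays, 3 from wild-type cells and 3 from cells lacking Satb1. Per the labels and the series' design, the cells were kept in serum medium with LIF and grown for 3 days on irradiated feeder cells with hygromycin, which selects for expression of a marker in the Oct4 locus, and most feeders were removed by letting the suspension settle before RNA extraction. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may in part be technical. The knockout arrays are numbered 1-1, 1-2 and 2-1 as clones in the labels, and the meaning of the first number is not given there. The numbers of the groups do not pair the arrays.

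The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA (background correction, normalization between arrays and summary of probes), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. The table held 35557 probe sets with no missing value, and array medians lay between 4.69 and 4.85. Arrays have no read depth, and the number of arrays limits the precision. Background correction and the floor of hybridisation signal compress the differences of dim genes, so that a log2 difference understates the change of a gene that is weakly expressed in 1 of the groups.

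Gene names came from the platform annotation supplied with the table, which listed 23410 of the probe sets. Of all probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 12147 had none. A probe set with several symbols or none was not used to name a gene. For each gene the probe set with the highest mean over all 6 arrays was kept, which left 19938 genes, 999 of which had more than 1 probe set. Chromosomes and gene order came from the RefSeq genes of assembly GRCm38.p6, in which 19853 of these genes were found by Entrez ID. The array's own genome build is not given in the sources used here, so that table served only for neighbourhood and no coordinate is printed.

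Knockout and wild type were compared with limma (version 3.58.1, R 4.3.3; lmFit and eBayes, no covariate, no filter on dim genes), and a gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Adjusted p-values in the text are from limma unless another test is named. Differences are knockout minus wild type on the log2 scale, with the moderated standard error (SE). In all, 23 gene lists with 353 entries, 321 of them measured, were fixed before the data were examined and tested with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The choice of groups, tests, lists, the rule for named genes and most alternatives was made before the data were examined. The rule named Satb1, the 12 genes with the largest difference in each direction among changed genes whose groups did not overlap, up to 4 changed members of each list, and fixed genes of pluripotency, feeder cells and sex chromosomes. Ddx3y, which the rule also named, was not analysed here.

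For shifts along chromosomes, the genes brighter than the median gene were ordered along each chromosome (9947 genes), and the median difference of each chromosome was set against 10000 random gene sets of the same size. A circular binary segmentation of the ordered differences, with 500 permutations for each segment and a p of at most 0.01, then looked for stretches of at least 10 brighter genes shifted by at least 0.2 from the median of these genes. Shorter segments were found but not counted as stretches. The Y chromosome, which has 4 brighter genes and was not segmented, was counted as a shifted stretch whole, without that minimum. The test by chromosome was planned, and the segmentation was added after seeing the data. The 12 genes with the largest difference in each direction outside the stretches found were also listed, by the same rule.

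The steps were tested on simulated data. With 200 changed genes planted among the 19938 genes in each of 5 simulated comparisons of 3 against 3 arrays, limma found 16.4% of changes of 0.5 log2 units, 93.5% of changes of 1 and 100% of changes of 2, and 4.9% of its calls were false. Camera found the 1 list that had been moved, and 0 lists in unmoved data. The noise in these limma and camera runs was drawn independently for each gene. They could therefore not show false calls that arise when genes vary together, as the real ones do (estimated correlation 0.176 in the naive pluripotency list). The segmentation found 8 of 10 planted stretches of 30 genes at 0.3, 10 of 10 of 20 genes at 0.5 and 9 of 10 of 90 genes at 0.8, and reported 1 stretch in 60 shuffled chromosomes. There, too, each gene was drawn independently, from the genes outside the stretches. The segmentation runs could therefore not show false stretches that arise when neighbouring genes vary together.

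Alternatives were eBayes with trend and robust settings, only genes above the median level, the mean of a gene's probe sets, a second quantile normalization, centring each array on its median, a floor at the 25th percentile, array weights, the mean of knockout arrays 1-1 and 1-2 as 1 sample, leaving out each array, all probe sets, stricter thresholds and limma's treat against a fold of 1.2. Leaving out the genes of the shifted stretches was added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.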

Results

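Expression was measured in ES cells, the cultured cells of the early mouse embryo that can form all its tissues. There were 3 wild-type arrays (replicates 1, 2 and 3) and 3 arrays of cells without Satb1 (replicates 1-1, 1-2 and 2-1). Satb1 is a DNA-binding protein that organises chromatin. The comparison bears on which genes depend on Satb1 in undifferentiated ES cells, among them Nanog and other regulators of pluripotency. It cannot separate loss of Satb1 from other differences between the knockout and wild-type cells, such as the chromosome shifts below. This holds also for changed genes that lie outside those shifts. Across all probe sets, Pearson's r was 0.976 to 0.986 within wild type, 0.989 to 0.991 within knockout and 0.981 to 0.987 between the groups. The median SD of a gene was 0.16 log2 units in wild type and 0.11 in knockout. The first principal component held 36.2% of the variance and separated the groups. The second held 29.4% and set wild-type replicate 3 (score -29.3) apart from the other 5 arrays, whose scores lay between 0.5 and 13.1.

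Satb1 itself was lower in the knockout arrays. Its only probe set, on chromosome 17, read 5.14 ± 0.16 (SD, n = 3) in wild type and 4.47 ± 0.10 (SD, n = 3) in knockout, a difference of -0.67 (SE 0.12, limma adjusted p = 0.022). All 3 knockout values (4.38, 4.47 and 4.57) lay below all 3 wild-type values (5.12, 4.99 and 5.31). Satb1 was weakly expressed in both groups, at percentile 45.6 of the genes tested. Whether the probes lie in the deleted part is not given in the sources used here, so the size of the drop does not check the knockout. Without wild-type replicate 1 or any one knockout array the difference lay between -0.72 and -0.62 and missed the threshold. The 30 genes around Satb1 had a median difference of -0.02 (range -0.26 to 0.64).

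In total, 184 genes were higher and 95 lower in the knockout arrays (limma, adjusted p under 0.05, of 19938 genes). Of these, 59 and 17 differed by at least 1 log2 unit. All 279 changed genes had groups that did not overlap, as did 3020 genes (15.1%) of all tested, where chance gives 10%. The counts depended on the arrays: leaving out 1 array gave between 74 and 356 higher and between 19 and 124 lower genes, with the most without wild-type replicate 3 and the fewest without a knockout array. A floor on dim values left 10 higher and 2 lower genes. It also left 4019 genes with no spread, which changed the variance estimate that limma shares among all genes.

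Many of the changed genes lay side by side on a few chromosomes. Chromosome stretches whose genes moved together held 142 of the 279 changed genes (50.9%) but 6.8% of the genes tested. The Y chromosome, counted whole with its 4 brighter genes, gave 5 of the 142. Because the stretches were found from the same differences as the changed genes, an excess of changed genes in them was built in. The largest shift upward covered the stretch of distal chromosome 6 from Dcp1b to Dera, in which 94 of 99 brighter genes were higher and the median difference was 0.86 (a fold of 1.82). It holds Nanog, Cd9, Cdkn1b, which encodes a cell cycle inhibitor, the glucose transporter gene Slc2a3 and the Wnt co-receptor gene Lrp6; Cd9, Cdkn1b and Slc2a3 were chosen after their values were seen. Of its 251 tested genes, 69 rose and 1 fell (Prp2, -0.87). Beyond it, from Plekha5 to Resf1, the direction turned: the median was -0.60, 1 of 29 brighter genes was higher and 16 genes fell. The 10 genes before Dcp1b had a median of 0.05.

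Chromosome 8 was lower along its whole length. Its 570 brighter genes had a median difference of -0.29, 7.72% of them were higher, and 36 of its 954 tested genes fell, with none rising. Among them were Apela (-1.19), which encodes a hormone-like peptide of ES cells, and Plcg2 (-1.06), which encodes a phospholipase; both were chosen after their values were seen. Chromosome 11 held 2 raised stretches. From Phykpl to Kif3a, 23 of 23 brighter genes were higher with a median of 0.57 and 10 genes rose. From Akap1 to Mmd, 10 of 10 were higher with a median of 0.44, and 2210409E12Rik (1.95) and Elobl (1.58) rose. Raised segments of 5 genes from Tns3 to Ddc (median 0.47) and from 0610010F05Rik to Papolg (median 0.52) were under the minimum length. A segment of 12 genes from Cep68 to B3gnt2 (median 0.21) was under the minimum shift from the median of brighter genes. The genes of these segments are counted outside the stretches. On chromosome 4, all 13 brighter genes from Slc44a1 to Lpar1 were higher (median 0.49), and Klf4 (0.97), Ctnnal1 (0.99) and Epb41l4b (0.54) rose; the latter pair, and Prp2 above, were named after their values were seen. Against random gene sets of the same size, the medians of chromosomes 8 and Y lay at percentile 0, that of chromosome 7 (-0.00) at 0.4, those of chromosomes 6 (0.08) and 9 (0.05) at 100, that of chromosome 12 (0.05) at 99.6 and that of chromosome 16 (0.04) at 98.2. The 9199 brighter genes outside all these stretches had a median difference of 0.03 (SD 0.22).

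Genes of the Y chromosome were lower in all knockout arrays. Eif2s3y read 7.78 ± 0.30 (SD, n = 3) in wild type and 5.51 ± 0.15 (SD, n = 3) in knockout (difference -2.26). Zfy1 (-1.65), Uty (-1.64), Uba1y (-1.40) and Kdm5d (-1.25) also fell, and 4 of 4 brighter Y genes had a median difference of -1.50. The other probe sets of Uba1y read -1.37, -0.46 and -0.46. Xist, the RNA that silences an X chromosome, was at a low level in both groups, 4.65 ± 0.24 against 4.85 ± 0.48 (SD, n = 3 each; limma adjusted p = 0.865), and the 291 brighter genes of the X chromosome had a median difference of 0.02. Set against the wild-type mean, the median of the chromosome 8 genes was -0.27, -0.31 and -0.28 in knockout replicates 1-1, 1-2 and 2-1, and that of the Y genes -1.45, -1.54 and -1.50.

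**Figure D1:**
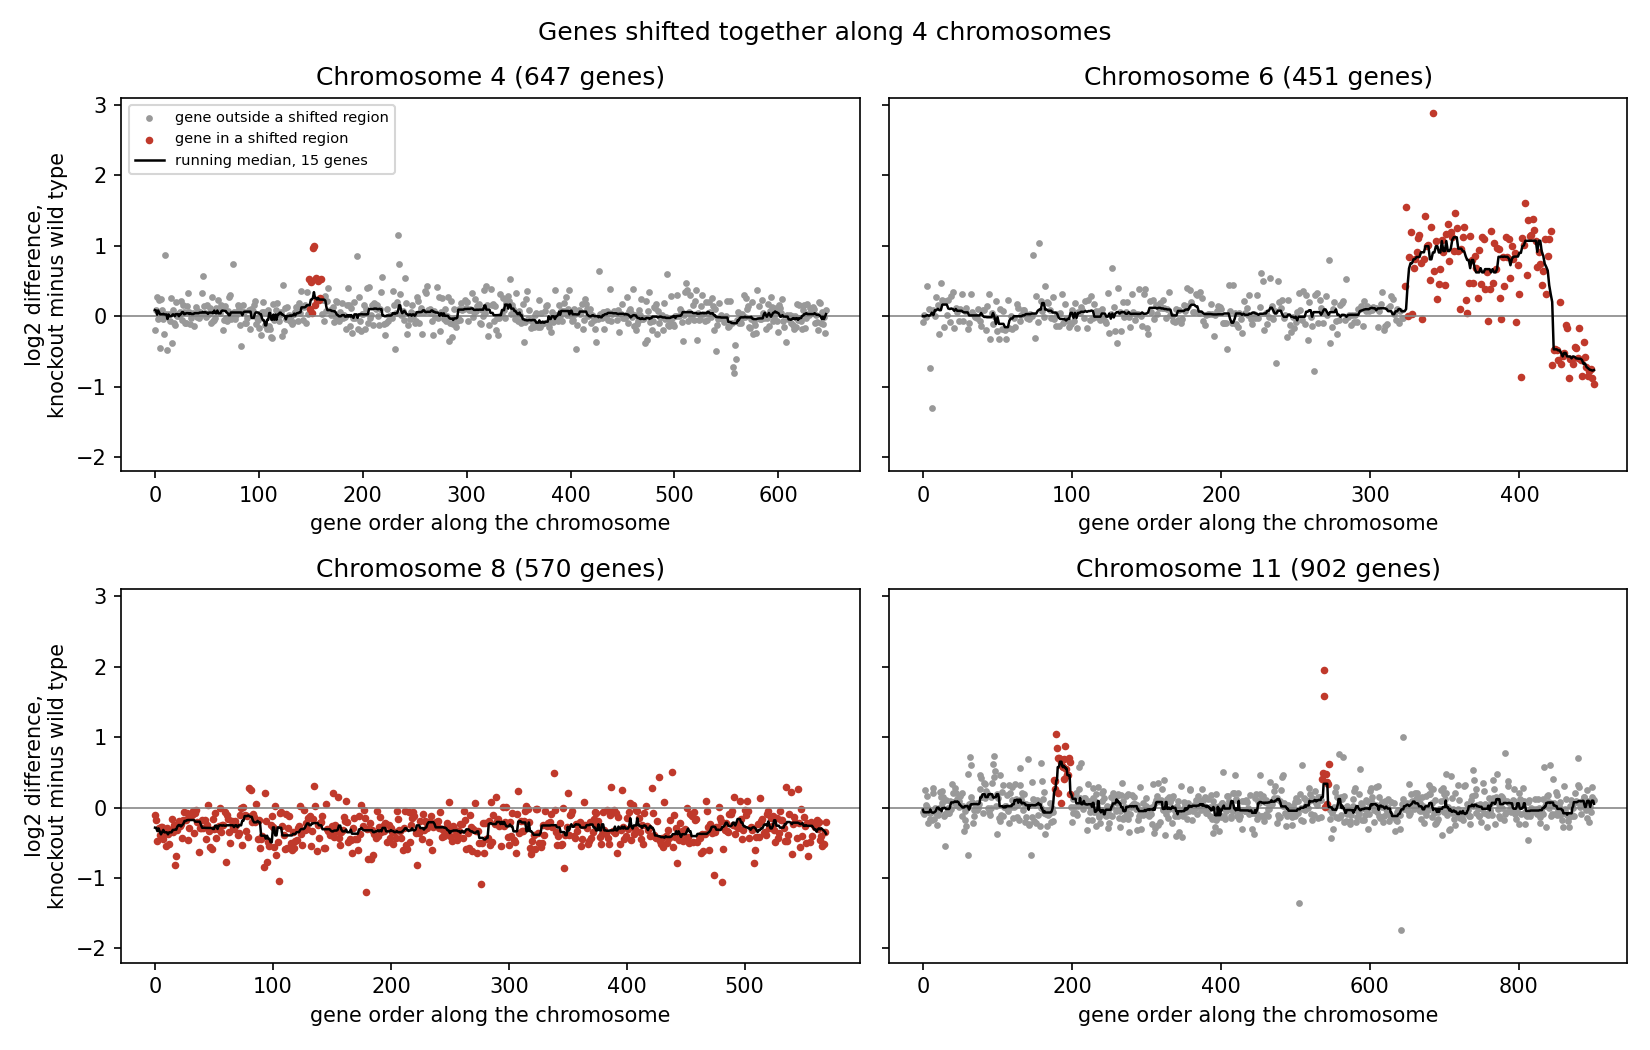
Log2 difference (knockout minus wild type, y axis) of each brighter gene in its order along chromosomes 4, 6, 8 and 11 (x axis); red points are genes of a shifted stretch, grey points other genes, and the black line is the running median of 15 genes. The end of chromosome 6 steps up to a median of 0.86 and then down to -0.60, and all of chromosome 8 lies around -0.29.

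Outside these stretches 100 genes rose and 37 fell. When only the genes outside them were tested, a choice made after seeing the data, 58 higher and 20 lower genes passed. The largest increase was that of Apoa2, which encodes an apolipoprotein of high-density lipoprotein, from 4.93 ± 0.08 to 7.38 ± 0.26 (SD, n = 3 each), a difference of 2.45 (SE 0.14, limma adjusted p = 8.57e-05). Serpinb6c rose by 1.83, the T-box factor Tbx3 by 1.59, Khdc3, a member of the oocyte and ES cell complex of KH-domain proteins, by 1.56, and Lama1, which encodes a laminin chain of basement membranes, by 1.53. Next came Cyct, the testis form of cytochrome c (1.44), Galnt11 (1.32), Nr5a2 (1.32), Rab27a, which acts in vesicle transport (1.18), Glo1 (1.17, second probe set 1.19) and Nup62cl (1.16). The chromosome of 1700024J04Rik (1.50) was not given by the RefSeq table, so whether it lies in a stretch is open, although it is counted outside them. Among all genes the largest increases also included A2m (2.89), Prmt8 (1.70), Lrp6 (1.60) and Adipor2 (1.55) of the chromosome 6 stretch. Elobl missed the threshold without wild-type replicate 1 or any one knockout array (1.36 to 1.62), Nup62cl without any one knockout array (1.12 to 1.22), and Serpinb6c without wild-type replicate 1 or knockout replicate 1-2 or 2-1 (1.59 to 1.82).

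Outside the stretches, keratin genes of simple epithelia had the largest decreases. Krt8 went from 9.23 ± 0.74 to 6.51 ± 0.41 (SD, n = 3 each), a difference of -2.72 (SE 0.32, limma adjusted p = 0.00209), its partner Krt18 one of -2.48 and Krt19 one of -1.74. Krt8 and Krt18 lie in a lower segment of chromosome 15 from Smim41 to Tns2 (8 brighter genes, median -0.37), and Krt19 ends a segment of 9 genes on chromosome 11 (median -0.17); both were under the minimum of 10 genes, from which only the Y chromosome was exempt, and so were not counted among the stretches. Wild-type replicate 3 had the highest Krt8 value (10.09, against 8.80 and 8.80), and the 3 keratin genes stayed past the threshold without it. Decreases were also found for AI506816 (-1.48), the carbonic anhydrase gene Car4 (-1.35), the retrotransposon-derived imprinted gene Peg10 (-1.30), the semaphorin gene Sema6a (-1.20), the neuronal intermediate filament gene Prph (-1.16), Fndc3c1 (-1.06), Zfp948 (-0.94), the DNA methyltransferase gene Dnmt3a (-0.94) and Peg3 (-0.92). Fndc3c1 missed the threshold without knockout replicate 1-2 or 2-1 (-0.98 and -1.06), and Zfp948 without knockout replicate 1-2 (-0.91).

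Naive pluripotency genes, which mark the ES cell state of the early epiblast, were higher as a group by camera (adjusted p = 3.21e-10), but not with an estimated correlation (adjusted p = 0.354) or by fry (adjusted p = 0.154). Camera with its preset correlation called 2 of the 23 lists, this one and the imprinted genes, and other splits of the same 6 arrays gave up to 6 lists. Of 23 measured members, 9 rose and 0 fell over all genes tested, or 11 and 2 adjusted over the list alone, and the median difference was 0.38, or 0.23 without wild-type replicate 1 and 0.45 without replicate 3. The list level was -0.35, -0.15 and 0.01 in wild-type replicates 1, 2 and 3 and 0.16 to 0.22 in the knockout arrays. Nanog rose from 9.87 ± 0.15 to 10.95 ± 0.04 (SD, n = 3 each), a difference of 1.09 (SE 0.11, limma adjusted p = 0.00109). It lies in the raised stretch of chromosome 6, at percentile 67.7 of the differences of its 99 brighter genes. Tbx3 (1.59), Nr5a2 (1.32), Prdm14 (1.09) and Esrrb (0.56) rose and lie outside the stretches, while Klf4 (0.97) lies in the raised stretch of chromosome 4, at percentile 84.6 of 13 genes. Pou5f1, the Oct4 gene whose locus carries the selection marker, read 10.22 in wild type and 9.83 in knockout (-0.39, limma adjusted p = 0.309), Sox2 differed by 0.30 (adjusted p = 0.317) and Zfp42 by -0.11 (adjusted p = 0.884). Zfp42 lies on the lowered chromosome 8, whose brighter genes had a median of -0.29. The 17 members outside the stretches had a median of 0.30, with 6 rising. Klf4 missed the threshold without any one array but wild-type replicate 3 (0.80 to 1.05), Esrrb without wild-type replicate 1 or any one knockout array (0.48 to 0.57), and Prdm14 without knockout replicate 1-2 or 2-1 (1.03 and 1.04).

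**Figure D2:**
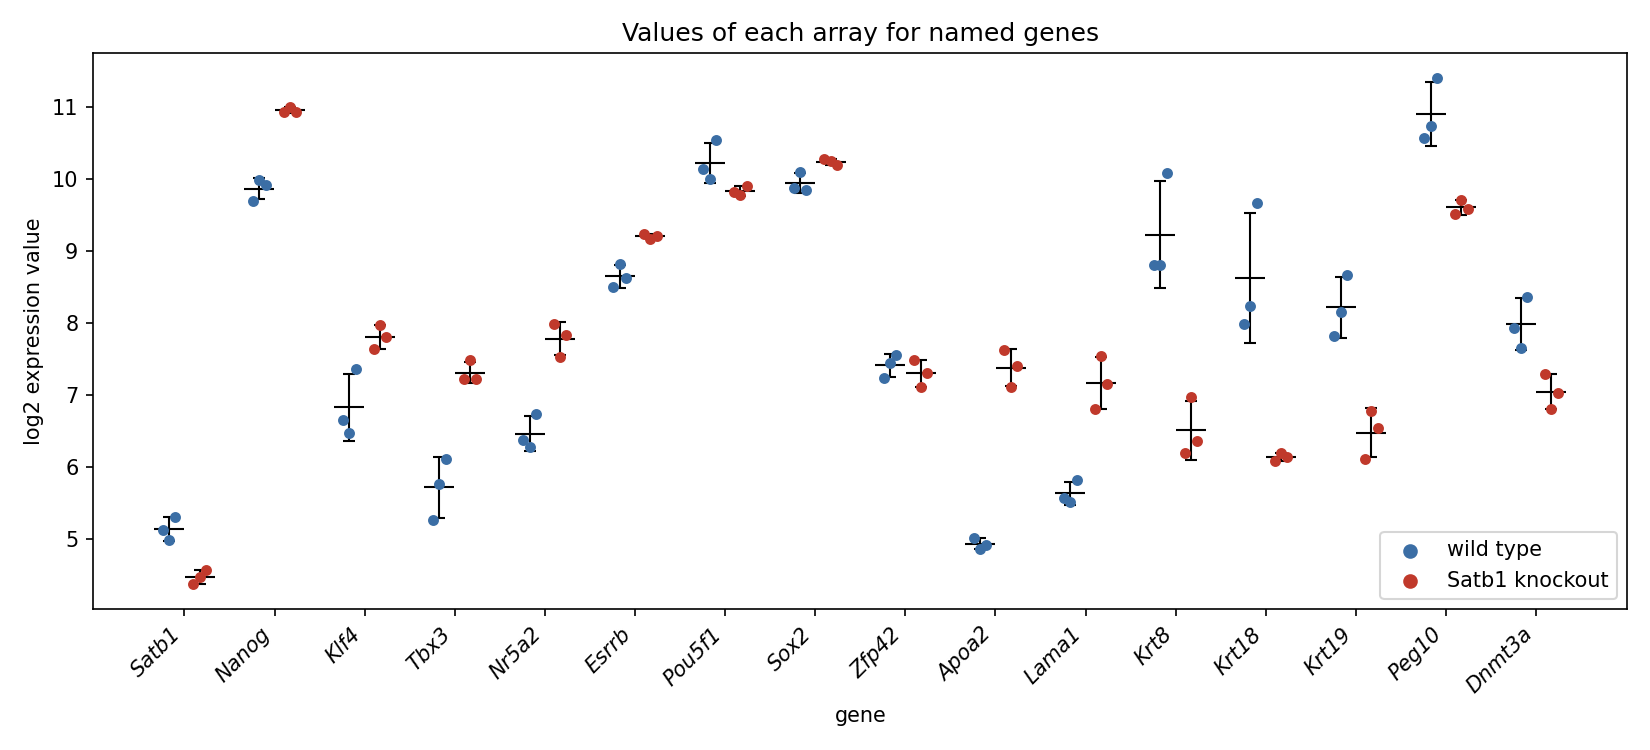
Log2 expression value (y axis) of 16 named genes (x axis) on each array; blue points are wild type, red points Satb1 knockout, and the black bars give the mean and SD of 3 arrays. Nanog stands at 10.95 in knockout against 9.87 in wild type, and Krt8 at 6.51 against 9.23.

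Imprinted genes, expressed from 1 parental copy, were lower as a group by camera (adjusted p = 0.0221), but not with an estimated correlation (adjusted p = 0.354) or by fry (adjusted p = 0.154). Of 17 measured members 2 fell, Peg10 and Peg3, and 0 rose, or 5 and 0 adjusted over the list alone, with a median of -0.12. The call by camera was also lost without knockout replicate 1-2 (median -0.07). None of the members lies in a shifted stretch. Peg10 missed the threshold without knockout replicate 1-1 or 2-1 (-1.25 and -1.29), and Peg3 without knockout replicate 1-1 or 1-2 (-0.94 and -0.85).

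Of the 15 primed epiblast genes, which mark the state that follows the naive one, 1 fell (Dnmt3a) and 0 rose, or 4 and 1 adjusted over the list alone, where Igfbp2 (0.99) was the 1 higher gene; the median was -0.16 (camera adjusted p = 0.0681, and 0.542 with an estimated correlation). The list passed the threshold without wild-type replicate 2 (adjusted p = 0.014) or knockout replicate 2-1 (median -0.16), above the median level, with each array centred, and outside the stretches (adjusted p = 0.0204, but 0.323 with an estimated correlation). Dnmt3a missed the threshold without wild-type replicate 1 or any one knockout array (-1.06 to -0.82). Among the signalling lists, the Nodal and BMP list and the LIF and STAT3 list each held 1 changed gene. Bmp4, a growth factor gene of the former, rose by 1.14, and the LIF feedback inhibitor gene Socs3 by 0.60, its second probe set reading 0.42. The FGF and ERK list and the Wnt list held 0 changed genes. Pramel7 of the 2-cell-like list rose by 1.13. Socs3 missed the threshold without wild-type replicate 1 or any one knockout array (0.55 to 0.66).

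With all arrays and genes, no list of other cell types passed the threshold by camera. In the trophectoderm list, of the outer layer of the blastocyst, Krt8 and Krt18 fell among 15 genes (median -0.16, adjusted p = 0.178), and the list passed the threshold without wild-type replicate 1 (median -0.26, adjusted p = 0.0433), outside the shifted stretches (median -0.20, adjusted p = 0.0204, but 0.671 with an estimated correlation) and among genes above the median level. Leaving out 1 array gave medians from -0.26 to -0.05. The median was -0.06 without wild-type replicate 3, whose list level (0.36) stood above those of replicates 1 (0.01) and 2 (-0.02), and -0.05 without knockout replicate 2-1. Adjusted over the list alone, 3 of its genes were lower and 3 higher, so the list did not move one way. The higher genes were Eomes (0.55), Tead4 (0.43, in the raised stretch of chromosome 6) and Tfap2c (0.33). Cdx2, a regulator of that layer chosen after its value was seen, read 4.60 and 4.37 (-0.23, limma adjusted p = 0.622). In the extraembryonic endoderm list Lama1 and Sparc (0.63) rose among 18 genes, and the median was -0.01 against a mean of 0.12 (adjusted p = 0.408). Gata2 (-0.67) of the blood and endothelium list (median -0.04, adjusted p = 0.265) and Nes (-0.58) of the neural list (median -0.02, adjusted p = 0.667) fell. The mesendoderm list had a median of 0.01 (adjusted p = 0.754) and the feeder fibroblast list, which marks cells of the feeder layer, 0.12 with 0 of 22 genes changed (adjusted p = 0.085). The feeder list passed without wild-type replicate 2 (median 0.08) or knockout replicate 1-2 (median 0.15, adjusted p = 0.00915). With all arrays, camera with an estimated correlation gave it an adjusted p of 0.793. Col1a1 differed by 0.12 and Col3a1 by 0.09 (limma adjusted p = 0.857 and 0.906). Sparc missed the threshold without wild-type replicate 1 or 2 or any one knockout array (0.55 to 0.66), Gata2 without wild-type replicate 1 or any one knockout array (-0.75 to -0.61), and Nes without any one of the 6 arrays (-0.66 to -0.49).

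**Figure D3:**
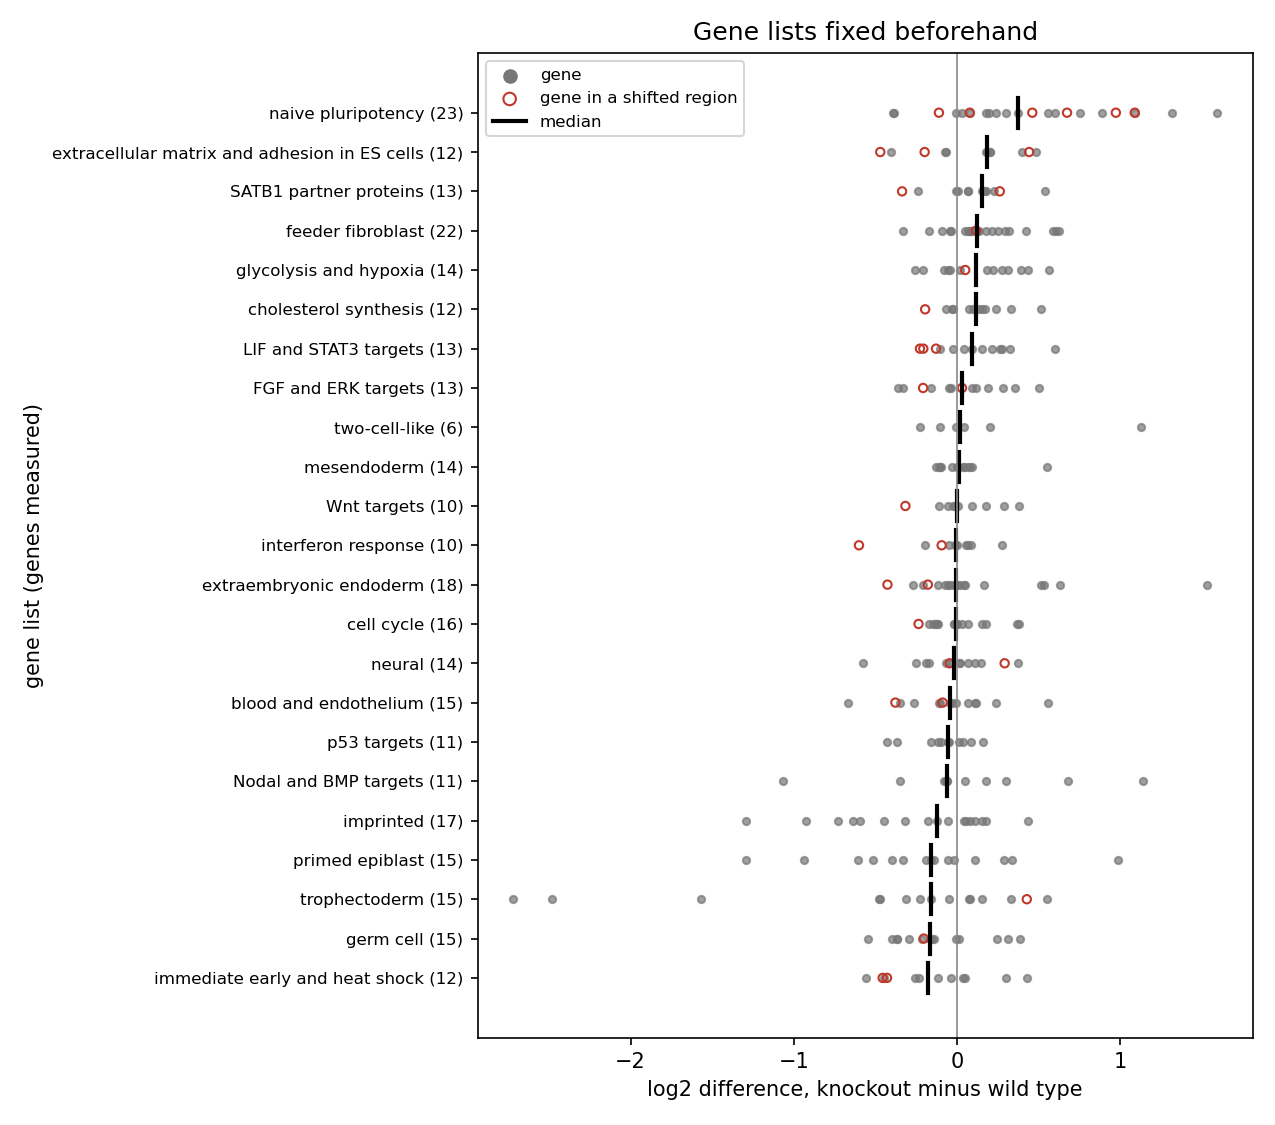
Log2 difference (knockout minus wild type, x axis) of each measured member of the 23 gene lists (y axis, with the number measured); grey points are genes, red circles genes of a shifted stretch, and black bars list medians. The naive pluripotency list has the highest median, 0.38.

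Between knockout replicate 2-1 and the mean of 1-1 and 1-2, the median absolute difference of a gene was 0.09 log2 units. This comparison rests on 1 array on one side, so it cannot show whether the knockout arrays differ beyond their spread.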

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

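Leaving out the genes of the shifted stretches was chosen after seeing the data. The counts of higher and lower genes (184 and 95) were 373 and 235 with array weights, 90 and 27 with the mean of knockout arrays 1-1 and 1-2 as 1 sample, 68 and 15 over all probe sets, 59 and 17 with a difference of at least 1, 86 and 23 at an adjusted p under 0.01, 74 and 20 with treat, and 58 and 20 without the shifted stretches. Leaving out 1 array gave 74 to 356 higher and 19 to 124 lower genes. The share of higher calls was 65.9%, against 56.9% (183 lower genes) after a second quantile normalization, 77.2% (47 lower) with each array centred and 83.3% with a floor, which gave 10 and 2. With the floor 4019 genes had no spread at all, and the prior degrees of freedom fell from 6.33 to 0.432. The 2 shifted lists became 4 above the median level and with centring, 1 with the floor and with the mean of 1-1 and 1-2, 5 without the stretches, 0 with an estimated correlation and 0 with fry, and 2 to 6 without 1 array. The mean of 1-1 and 1-2 and each left-out array test fewer samples by construction. For the other settings, apart from what is said of the floor below, the cause was not tested. Satb1 missed the threshold with the floor (-0.67) and with the mean of 1-1 and 1-2 (-0.64), and lay between -0.74 and -0.58 without 1 array. The median of the LIF and STAT3 target list turned from 0.09 to -0.056 with array weights and -0.030 without wild-type replicate 1 (-0.030 to 0.17 without 1 array), and Xist from 0.20 to -0.064 without knockout replicate 1-1 (-0.064 to 0.40 without 1 array); the cause was not tested. Of 45 changed named genes 30 kept their call without any one array, but 2 of the 45, Galnt11 and AI506816, kept it in every alternative that tested them. With the floor Nanog, Apoa2, A2m, Krt8 and Tbx3 were among those that lost it. All their values lay above the floor (3.86) and did not change. Their calls were lost through the altered fit of the other genes, not because they rest on dim values. No paired analysis was possible because the groups share no replicate numbers. The block of 1-1 and 1-2 could not be fitted with 1 pair among 6 arrays, and no probe set had the ID endings of the alternative that drops them, so neither was run.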

Other observations

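Tests of copy number, of regulation of a whole stretch, of active X chromosomes, of list members in the stretches and of all pluripotency genes rising alike were chosen only after the result was seen. Median differences were 0.18 for extracellular matrix and adhesion in ES cells, 0.15 for SATB1 partner proteins, 0.12 for glycolysis and hypoxia, 0.11 for cholesterol synthesis and 0.03 for FGF and ERK targets. They were -0.01 for cell cycle (mean 0.01), -0.01 for interferon response, -0.06 for p53 targets, -0.17 for germ cell genes and -0.18 for immediate early and heat shock genes. None of these 10 lists held a gene past the threshold over all genes tested. The Wnt target list had a median of -0.00 and a mean of 0.04. The Nodal and BMP list had a median of -0.06, a mean of 0.06 and camera's direction upward, the LIF and STAT3 list a median of 0.09 and the 2-cell-like list a median of 0.02. Camera's adjusted p over these lists lay between 0.0681 and 0.999. Outside the shifted stretches camera called 5 lists, the naive pluripotency, imprinted, LIF and STAT3, primed epiblast and trophectoderm lists, and 0 with an estimated correlation.

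The genes of distal chromosome 6 moved in opposite directions on either side of Dera. If the authors' normalization had moved genes by their mean level, genes elsewhere would have moved too. The 128 genes elsewhere with the same mean levels had a median difference of 0.05 (0.0454). They were drawn only from outside the stretches, where the median of the normalized values was 0.03. A small value was thus likely from the start, and the test says little about normalization. Genes of the raised stretch did not move alike: the quartiles of their differences were 0.47 and 1.12. The SD was 0.48 there, against 0.26 in the lower stretch and 0.22 among brighter genes outside the stretches. A difference in copy number between the knockout and wild-type cells may account for both steps, but an equal change of each gene would not give this spread. The dimmer genes, which were not used to find the stretches, also moved with them: 83.6% were higher in the raised stretch, against 43.6% of dimmer genes elsewhere, and 76.9% were lower in the other (95% Wilson interval 61.7 to 87.4), against 56.4% elsewhere. Regulation of the whole stretch by Satb1 cannot be told apart from it, because expression from 1 genotype contrast holds no measure of DNA; Nanog stood at percentile 67.7 of its stretch, among its neighbours.

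Chromosome 8 and the Y chromosome were lower in all knockout arrays. For normalization the same limit holds: 570 genes of the same mean levels, also drawn only from outside the stretches, had a median difference of 0.04 (0.0397). A difference in copy number of chromosome 8 is a candidate explanation: of its 384 dimmer genes, which the chromosome medians did not use, 80.2% were lower (95% Wilson interval 75.9 to 83.9), against 56.4% elsewhere. Which group carries the change is open, and regulation of the whole chromosome would give the same values. Knockout cells with 2 active X chromosomes are argued against by the median difference of 0.02 (0.0229; 95% bootstrap interval -0.02 to 0.06) of 291 X-linked genes. No effect of Satb1 itself on these chromosomes was tested.

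The naive pluripotency list was higher in knockout arrays by camera, but not with an estimated correlation (adjusted p = 0.354) or by fry (adjusted p = 0.154). Its rise was not confined to members in the shifted stretches, since 6 of the 17 others rose, with a median of 0.30. Whether raised genes of the stretches, Nanog and Klf4 among them, act on genes outside was not tested. The stretches can therefore not be excluded as a cause. The 6 members outside were called with adjustment over all genes, those of the stretches included. When only genes outside the stretches were tested, 78 of the 137 calls there were kept. Camera gave the 17 members outside adjusted p = 7.3e-08, but adjusted p = 0.323 with an estimated correlation, so that their shift as a list stays uncertain. A lower share of differentiated cells that raised all its genes alike is argued against, but only weakly, by 2 abundant members, Pou5f1 and Dppa4. They were lower past the threshold adjusted over the list alone (limma adjusted p = 0.035 and 0.023). Over all genes tested neither passed (limma adjusted p = 0.309 and 0.234), and Pou5f1 lay between -0.50 and -0.23 without 1 array. Whether fewer differentiated cells contributed is open: 67 markers of 5 differentiated types had a pooled median of -0.02 (-0.0189; 95% bootstrap interval -0.07 to 0.01) with members going both ways. Both groups were grown with hygromycin, which by the design selects for cells expressing Oct4 and so works against differentiated cells; how complete that selection was is not measured. Loss of Satb1 stays among the open explanations, as the design's own contrast, and no test here separates it from the rest.

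Among the 10 splits of the 6 arrays into 3 and 3, 1 split (the real one) gave as many as 279 changed genes, and the highest of the other splits gave 0. For shifted lists by camera, 9 splits gave at least the 2 of the real one, and the highest other gave 6. With 10 splits no share under 0.05 can be reached.

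Nnt, which carries a deletion in C57BL/6J mice, was lower in knockout (7.43 against 6.53, difference -0.90, limma adjusted p = 0.00269), and Glo1, which is duplicated in some inbred strains, was higher (8.04 against 9.21). Both were chosen for strain variation after their values were seen, and the strains of the cells are not given in the sources used here.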
